A study of Mus musculus with 9 samples.

How the data were processed

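Bone marrow cells of C57BL/6 mice with AML1-ETO9a leukaemia had been sorted into 3 populations by CD43 and c-Kit. RNA-seq libraries were made from total RNA with an Illumina TruSeq kit, per the labels' protocols. The deposited table holds whole-number read counts per gene symbol for 9 libraries, 3 per population. CASAVA 1.8, TopHat2 2.0.4, RSEM, HTSeq and edgeR are named, without their roles, per the submitters' processing notes. BWA and Cufflinks are also named in the design text of the series. The deposited table is titled as HTSeq counts, and the role of the other tools is not stated. The genome build named in those notes is human, while the rows carry mouse symbols, so the build and annotation of the counts are not given in the sources used here. No coordinates are printed for that reason. Strand handling is not stated either, so counts of overlapping and antisense genes, and of genes with near-identical copies, are uncertain.

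The table had 24391 gene rows, of which 6162 had 0 counts in all libraries. Of the rows, 27 carried dates in place of gene symbols, and 2 of these names occurred in 2 rows each. They stayed in the fit and are not named. No row held a mitochondrially encoded or immunoglobulin gene. Total counts ranged from 17966197 to 31781746. The 10 most abundant genes held 4.29% to 4.80% of counts in CD43++ckit+, 5.43% to 5.65% in CD43+ckit- and 12.2% to 14.1% in CD43-ckit-. TMM factors ranged from 0.589 to 1.41. Counts of each pair of libraries within a population differed by more than sampling noise (chi-square per degree of freedom 16.0 to 124.8), so none was treated as a duplicate of another. This does not show that they came from separate animals.

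Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 12573, and were scaled by TMM. A model of 3 group means was fitted to all 9 libraries (estimateDisp, robust glmQLFit, glmQLFTest). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each of the 3 pairwise comparisons and in the joint test. The standard error of a log2 fold change was approximated as its size divided by the square root of the F statistic. CPM values are TMM-scaled.

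The design, the rule for named genes and 23 gene lists were fixed before the data were examined. The lists held progenitor, AML1-ETO associated, primary granule, neutrophil maturation, monocyte and macrophage, dendritic cell and MHC class II, erythroid, B-lineage, plasma cell, T and NK cell, megakaryocyte, and mast cell, basophil and eosinophil genes. Others held stroma and endothelium, DNA replication, mitosis, MYC and ribosome biogenesis, mitochondrial respiration, glycolysis, interferon response, immediate early and heat shock, BCL2 family, adhesion and homing, and lysosome and phagocytosis genes. Some members, such as Ly6g, Ahsp and the immunoglobulin genes, had no row and were not analysed here. Lists were tested with limma 3.58.1, by camera on voom values with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation was run beside it, under which no list kept its call. Fry was also run, which tests whether a list moves on balance in one direction without comparing it with other genes. Under fry 54 list results were unchanged, 6 lost the call, 8 gained one and 1 turned direction without a call. Between CD43+ckit- and CD43-ckit- the neutrophil, erythroid and T and NK cell lists lost it (fry adjusted p = 0.122, 0.122 and 0.293). The megakaryocyte list gained it there (0.0156). For CD43++ckit+ versus CD43+ckit- the glycolysis, immediate early and T and NK cell lists lost it (fry adjusted p = 0.052, 0.052 and 0.152). In that comparison the megakaryocyte, mast cell and BCL2 family lists gained it (0.01, 0.00628 and 0.00393). For CD43++ckit+ versus CD43-ckit- the progenitor, AML1-ETO associated, plasma cell and megakaryocyte lists gained it (largest fry adjusted p = 0.00584).

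The text names Kit, Spn, Runx1 and Runx1t1. It draws the rest from the 8 largest changes in each direction among called genes with an average log2 CPM of at least 3 and no overlap between libraries, predicted genes left out. From each list it draws on the 4 members with the smallest adjusted p and an average log2 CPM of at least 1, and from the genes that set CD43++ckit+ apart from both others on 6 in each direction. Some genes that this rule takes are not reported here.

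Replicate numbers are shared between populations in the labels. Deviations from the group means of same-numbered libraries correlated at 0.506, 0.349 and 0.283 between CD43+ckit- and CD43-ckit-. The highest correlations with a differently numbered library were -0.382, 0.321 and 0.322, the last above that of its own number. By the rule set for this check (each above 0.1) the numbers were taken to pair those populations. The deviations within a population cancel, and library 1 correlated least with the others in both populations. That library alone could meet the rule, so the rule does not show pairing. The labels give no origin for the pairing, so it stays an assumption, and the blocked value is given where it changed a call.

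The procedure was tested on simulated counts for the 12573 genes, with 100 genes changed 2-fold and 100 changed 4-fold. Counts were drawn independently for each gene, with its mean over the 9 libraries and the real library sizes. In the simulation of CD43++ckit+ versus CD43+ckit-, 34% of the 2-fold and 72% of the 4-fold changes were recovered, and 7.02% of calls were false. For CD43++ckit+ versus CD43-ckit- these shares were 30%, 83% and 5.83%. For CD43+ckit- versus CD43-ckit- they were 28%, 67% and 6.86%. The real comparisons called 39.8% to 67.4% of genes, and genes of some lists vary together. The simulated shares therefore need not hold for the real data.

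The alternatives were DESeq2 size factors, library totals, no low-count filter, a strict filter, a 2-fold minimum, DESeq2 1.42.0, limma-voom, a non-robust fit, fits of the 2 groups compared, a replicate block, leaving out haemoglobin, immunoglobulin and mitochondrial genes, and leaving out each library. Added after the data were seen were a block within the 2 groups compared, the neutrophil list mean as a covariate, leaving out the least correlated library of each population, and counts thinned to the smallest total.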

Results

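RNA-seq gene counts were available for 9 libraries from bone marrow cells of mice with leukaemia driven by AML1-ETO9a, a short splice form of the AML1-ETO fusion protein. The cells had been sorted into 3 populations by surface CD43 and c-Kit, with 3 libraries each: CD43++ckit+, CD43+ckit- and CD43-ckit-. CD43 is a sialoglycoprotein of leukocytes and c-Kit is the stem cell factor receptor found on progenitors. Total counts per library ranged from 17966197 to 31781746, and the 3 CD43-ckit- libraries were the shallowest (17966197 to 21609537). The comparisons ask how the transcriptomes of the 3 sorted populations differ. Log2 fold changes are given as the first-named population minus the second, and adjusted p-values come from edgeR's quasi-likelihood test. Nothing in the labels says that the 3 libraries of a population came from separate animals, so p-values measure the spread between these samples, which may be technical.

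Kit, which encodes c-Kit, had a mean of 164.2 ± 15.9 CPM (SD, n = 3) in CD43++ckit+, 15.8 ± 7.01 CPM in CD43+ckit- and 34.1 ± 13.2 CPM in CD43-ckit-. Kit was higher in CD43++ckit+ than in CD43+ckit- (log2 fold change 3.38, adjusted p = 0.000569) and than in CD43-ckit- (2.27, adjusted p = 0.000897). Between the populations sorted as c-Kit negative it was lower in CD43+ckit- than in CD43-ckit- (-1.11, adjusted p = 0.0379). That call was lost with library totals (adjusted p = 0.330) and without a low-count filter (0.0792). It was also lost without library 1 of CD43++ckit+, library 1 or 2 of CD43+ckit- or library 2 or 3 of CD43-ckit- (adjusted p from 0.0542 to 0.114). Spn, which encodes CD43, stood at 502.4 ± 63.7, 194.2 ± 50.3 and 142.3 ± 61.2 CPM in the same order. Spn was higher in CD43++ckit+ than in CD43+ckit- (1.37, adjusted p = 0.0109) and than in CD43-ckit- (1.82, adjusted p = 0.00132). Between CD43+ckit- and CD43-ckit- the Spn difference was 0.45 (adjusted p = 0.269). It passed the threshold with same-numbered libraries as blocks in a fit of these 2 populations (adjusted p = 0.0168) but not with blocks over all 9 libraries, and it passed with library totals (0.0443) and without the least correlated library of each population (0.0159). Runx1 and Runx1t1 are the mouse genes of the fusion partners. Runx1t1 was lower in CD43++ckit+ than in CD43+ckit- (-0.62, adjusted p = 0.032), and against CD43-ckit- its value was 0.00 (adjusted p = 0.996). The Runx1t1 call was lost with library totals (adjusted p = 0.0633). It was also lost without library 2 or 3 of CD43++ckit+ or any one of the CD43+ckit- libraries (adjusted p from 0.0527 to 0.0906). Against CD43-ckit- its value became 0.93 with library totals. Runx1 was higher in CD43++ckit+ than in CD43+ckit- (0.92, adjusted p = 0.0312). That call was lost without library 1 or 2 of CD43++ckit+ or any one of the CD43+ckit- libraries (adjusted p from 0.0654 to 0.124). Against CD43-ckit- the Runx1 difference was 0.66 (adjusted p = 0.0663), and it passed the threshold with library totals (0.000254), without a low-count filter (0.0358) and without library 3 of CD43++ckit+ (0.00146) or library 1 of CD43-ckit- (0.0483). Runx1t1 was higher in CD43+ckit- than in CD43-ckit- (0.62, adjusted p = 0.0266). That call was lost with DESeq2 size factors (adjusted p = 0.0821) and without library 2 or 3 of either population (adjusted p from 0.0669 to 0.0918). Gene counts cannot separate a fusion transcript from the endogenous genes.

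**Figure D1:**
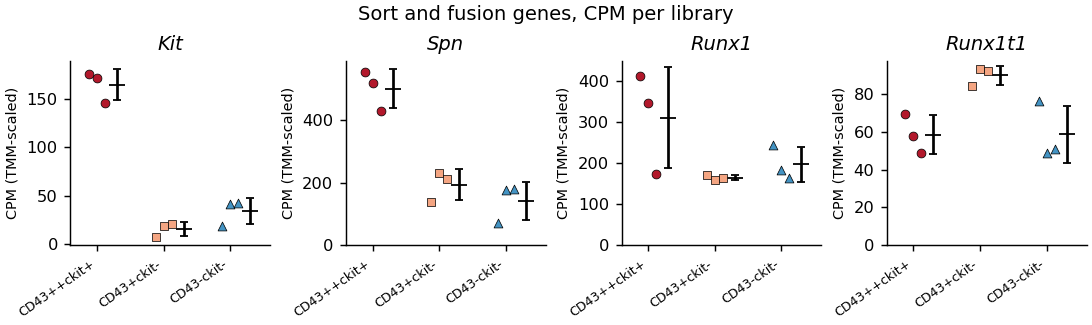
CPM per library (y axis, TMM-scaled) of Kit, Spn, Runx1 and Runx1t1 in the 3 populations (x axis), with points for libraries and bars for mean ± SD of 3 libraries. The 3 CD43++ckit+ libraries lie above the other 6 for Kit and Spn.

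The 3 populations separated on the first 2 principal components, which held 68.0% and 15.4% of the variance. Of 12573 tested genes, 9401 (74.8%) differed among the populations in the joint test. For 5905 of these the CD43+ckit- mean lay between the other 2 means (62.8%), and it was highest for 2118 and lowest for 1378. Genes called in both steps from CD43++ckit+ to CD43+ckit- to CD43-ckit- numbered 724 with falling and 936 with rising expression.

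**Figure D2:**
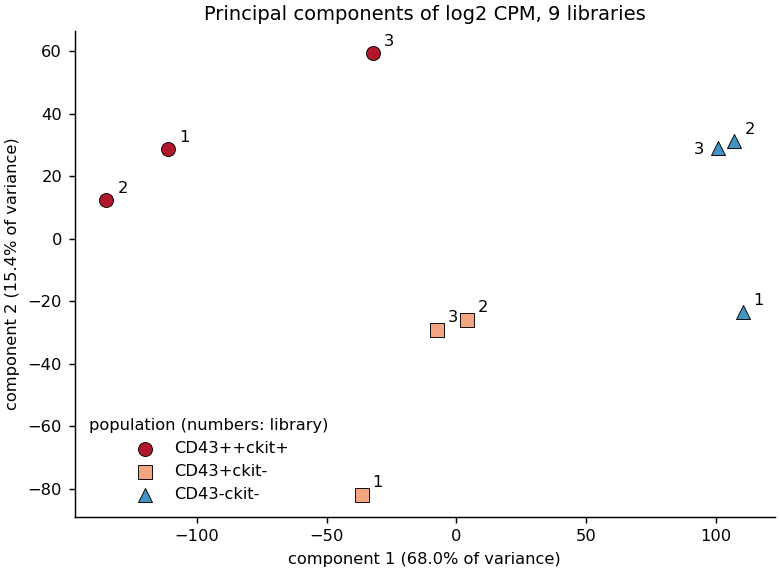
Principal components of log2 CPM, with component 1 on the x axis (68.0% of variance) and component 2 on the y axis (15.4%). Each point is a library, coloured by population and numbered by replicate. On component 1 the CD43-ckit- libraries lie apart from the other 6, while library 3 of CD43++ckit+ (-32.1) and library 1 of CD43+ckit- (-36.5) overlap the other population and are parted on component 2.

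Compared with CD43+ckit-, CD43++ckit+ cells had more transcript of ribosome production genes and of 8 mast cell, basophil and eosinophil genes, and less of erythroid and interferon response genes. The largest increases were in Muc13, a cell-surface mucin (log2 fold change 4.91 ± 0.69 SE, adjusted p = 0.000935), Papss2 (3.86), which makes the sulfate donor of sulfation reactions, Tph1 (3.65), the tryptophan hydroxylase of serotonin synthesis, and Ms4a2, the beta chain of the high-affinity IgE receptor (3.56 ± 0.41 SE; 294.5 ± 135.5 against 25.0 ± 2.11 CPM, SD, n = 3). The largest decreases were in Adam33 (-5.70), the endopeptidase gene Mmel1 (-5.34), Btnl10 (-5.20), the theta globin gene Hbq1b (-4.97), Alas2, the erythroid enzyme that starts haem synthesis (-4.83 ± 0.51 SE), and Chga, which encodes chromogranin A (-4.81). The rule for named genes required that the 3 libraries of each population did not overlap, which held for 55.5% of all tested genes. Hbq1b has a close copy, Hbq1a, and 71.7% of its 50-base words occur in no other gene of the reference transcripts, so part of its counts is uncertain.

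Of 30 erythroid genes, 28 were lower in CD43++ckit+ than in CD43+ckit- and 1 was higher (29 lower and 1 higher when adjusted over the list alone), with a median of -1.88 (camera adjusted p = 3.88e-13; adjusted p = 0.627 with an estimated correlation). Bpgm, the red cell bisphosphoglycerate mutase (-3.07), Tspan33 (-2.30) and Rhd (-2.25) were among them. Interferon response genes were lower for 26 of 31 members and higher for 0 (26 and 0 adjusted over the list alone), including Ifit1 (-3.78), Isg15 (-3.54) and Ifi27l2a (-3.26), with a list median of -1.52 (camera adjusted p = 2.73e-10; adjusted p = 0.627 with an estimated correlation). In contrast, 28 of 30 MYC and ribosome biogenesis genes were higher and 0 lower (29 and 0 adjusted over the list alone), with a median of 1.58 (camera adjusted p = 1.19e-11; adjusted p = 0.627 with an estimated correlation). Rrs1 (2.12), Wdr43 (2.03), Hspd1 (1.92) and Nop2 (1.64) illustrate this list. Glycolysis genes were higher for 12 and lower for 1 of 20 (13 and 2 adjusted over the list alone; camera adjusted p = 0.0136; adjusted p = 0.983 with an estimated correlation). Pfkfb3 (2.26), Pfkp (1.97) and Tpi1 (1.41) were higher, and the glucose transporter gene Slc2a1 was lower (-3.38). Fry did not call the glycolysis list (fry adjusted p = 0.052).

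Mast cell, basophil and eosinophil genes were higher for 8 of 18 members and lower for 0 (8 and 0 adjusted over the list alone), among them Hdc, the histamine-forming enzyme (1.84), and Il1rl1, the IL-33 receptor (1.04). The list missed the threshold (camera adjusted p = 0.0754) and was called without library 2 of CD43++ckit+ (adjusted p = 0.0261) and with the neutrophil list mean as a covariate (0.00266). The neutrophil maturation list also missed it (camera adjusted p = 0.0754). Without library 3 of CD43++ckit+ or library 1 of CD43+ckit- it was called lower in CD43++ckit+ (adjusted p = 0.000139 and 0.00109), and also with library totals (0.00746). Myb (2.14) and Cdk6 (2.47), genes of progenitor proliferation, were higher, as were Cbfb (3.06), whose product binds RUNX1, and Runx3 (2.73). Lmo2 (-1.46) and Adgrg1 (-1.33) of the progenitor list were lower, as were Nfe2 (-1.43) and Jup (-1.065) of the AML1-ETO associated list. The progenitor list had 7 members higher and 4 lower of 25, and the AML1-ETO associated list 8 and 4 of 20 (the same numbers adjusted over each list alone), and neither list was called. Bcl2 was higher (2.87), while Bcl2l1, which encodes the survival protein BCL-XL (-2.37), the pro-apoptotic Bbc3 (-2.15) and Mcl1 (-0.89) were lower; of 13 BCL2 family genes 1 was higher and 6 lower, also when adjusted over the list alone (camera adjusted p = 0.0754). The replication and mitosis lists were not called (camera adjusted p = 0.669 and 0.591): 0 of 32 replication genes were higher and 2 lower, and 0 of 32 mitosis genes were higher and 5 lower (0 and 2, and 0 and 4, adjusted over each list alone). Immediate early and heat shock genes were lower for 6 and higher for 2 of 22, also when adjusted over the list alone (camera adjusted p = 0.0371; adjusted p = 0.983 with an estimated correlation), and the T and NK cell list was called with 1 of its 24 members lower (also 1 adjusted over the list alone), Lck (-2.50; camera adjusted p = 0.027; adjusted p = 0.983 with an estimated correlation). Both calls were lost with DESeq2 size factors (adjusted p = 0.0544 for each) and with the strict low-count filter (0.0805 and 0.648). The stress list also lost its call without library 3 of CD43++ckit+ (adjusted p = 0.0862) or library 1 of CD43-ckit- (0.0577). The T and NK list lost it without library 2 of CD43++ckit+ (adjusted p = 0.171) or of CD43+ckit- (0.0624).

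In this comparison 5005 genes were called, 2472 higher and 2533 lower in CD43++ckit+, and 2676 of them changed at least 2-fold. Higher calls made up 49.4% with TMM scaling and 67.0% with library totals. Without the library of each population that correlated least with the other 2 (library 3 of CD43++ckit+ and library 1 of the others), 8557 genes were called.

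Against CD43-ckit-, CD43++ckit+ cells had more transcript of genes of ribosome production, DNA replication, mitosis and respiration, and less of erythroid, interferon response and stress genes. B-lineage and dendritic cell genes were also lower, at low levels given below. The largest increases were in C2cd4a (4.49 ± 0.66 SE), Tgfa, an EGF receptor ligand (3.47), Tph1 (3.33), Muc13 (3.25) and Arpp21 (3.25). Podxl, a sialomucin (3.09), Adgrg7 (3.06) and Ms4a2 (3.05) followed. Larger changes went the other way: Vgf, a neuropeptide precursor (-8.77), Tecta (-8.50), the skeletal muscle actin gene Acta1 (-8.25) and Chga (-8.18). Chga averaged 137.9 ± 110.2 CPM in CD43++ckit+, 3874 ± 581 CPM in CD43+ckit- and 40093 ± 9654 CPM in CD43-ckit- (SD, n = 3). Vgf averaged 1.47 ± 0.42, 7.55 ± 5.30 and 646.0 ± 119.0 CPM in that order.

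Erythroid genes were lower in CD43++ckit+ for 26 of 30 members and higher for 2 (26 and 2 adjusted over the list alone), with a median of -2.15 (camera adjusted p = 4.40e-09; adjusted p = 0.446 with an estimated correlation); Alas2 rose from 72.9 ± 53.4 CPM in CD43++ckit+ to 9121 ± 2014 CPM in CD43-ckit- (SD, n = 3; log2 fold change -6.97) and Bpgm differed by -6.88. Interferon response genes were lower for 30 of 31 and higher for 0 (30 and 0 adjusted over the list alone), with Isg15 at -6.94 and Ifit1 at -6.30 (camera adjusted p = 7.09e-10; adjusted p = 0.446 with an estimated correlation). Immediate early and heat shock genes were lower for 17 of 22 and higher for 0 (17 and 0 adjusted over the list alone), including Ppp1r15a (-5.70), Btg2 (-5.05) and Zfp36 (-4.74), with a median of -2.72 (camera adjusted p = 1.32e-06; adjusted p = 0.446 with an estimated correlation). MYC and ribosome biogenesis genes were higher for 28 of 30 and lower for 2 (28 and 2 adjusted over the list alone), with a median of 1.96; Wdr43 was at 2.41 (camera adjusted p = 1.32e-06; adjusted p = 0.446 with an estimated correlation). DNA replication genes were higher for 30 of 32 and lower for 2 (30 and 2 adjusted over the list alone), with a median of 1.49 (camera adjusted p = 2.64e-06; adjusted p = 0.446 with an estimated correlation); Mcm6 (1.69), Mcm10 (1.23) and Rrm1 (1.05) were higher. Mitosis genes were higher for 28 of 32 and lower for 2 (29 and 2 adjusted over the list alone), with Tpx2 (1.39) and Ccna2 (1.07) higher and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, lower (-3.89; camera adjusted p = 0.000122; adjusted p = 0.446 with an estimated correlation). Respiration genes were higher for 23 and lower for 2 of 32 (24 and 2 adjusted over the list alone), led by Ndufa9 (1.02), Idh3a (2.13) and Cycs (1.27) (camera adjusted p = 0.000975; adjusted p = 0.446 with an estimated correlation).

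B-lineage genes were lower in CD43++ckit+ for 22 of 23 (also 22 adjusted over the list alone), among them Ebf1 (-3.40), camera adjusted p = 1.04e-05; dendritic cell and MHC class II genes were lower for 13 of 16 (15 adjusted over the list alone), camera adjusted p = 0.000182. Both lists had adjusted p = 0.446 with an estimated correlation. T and NK cell genes were lower for 16 and higher for 1 of 24 (17 and 1 adjusted over the list alone; camera adjusted p = 0.000637), and monocyte and macrophage genes were lower for 11 of 28 (7 adjusted over the list alone), led by Lgmn, a lysosomal protease (-7.49; camera adjusted p = 2.82e-05). These lists, too, had adjusted p = 0.446 with an estimated correlation. Of 31 neutrophil maturation genes 5 were lower (1 adjusted over the list alone), among them Mxd1 (-5.21), a MYC antagonist, with a list median of -2.57 (camera adjusted p = 6.01e-05; adjusted p = 0.458 with an estimated correlation). Of 14 primary granule genes 1 was lower and 1 higher (the same adjusted over the list alone; camera adjusted p = 0.0211), and of 13 stroma and endothelium genes 4 were lower (3 adjusted over the list alone; camera adjusted p = 0.0124), with adjusted p = 0.446 with an estimated correlation for each. Per library, the mean of the neutrophil list in log2 CPM was 2.64, 1.15 and 6.15 in CD43++ckit+, 3.08, 5.89 and 5.62 in CD43+ckit-, and 5.82, 7.89 and 7.88 in CD43-ckit-. With that mean as a covariate, a fit added after the data were seen, 10 lists were called in place of 17. The neutrophil, primary granule, monocyte, T and NK cell, stroma, adhesion and lysosome lists were then no longer called, and neither was Muc13 (adjusted p = 0.0758).

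BCL2 family genes were lower for 7 of 13 (also 7 adjusted over the list alone), with Bcl2l1 at -5.27, Bbc3 at -5.19 and Bax, a pro-apoptotic member, at -2.10 (camera adjusted p = 0.0174). Adhesion and homing genes were lower for 11 and higher for 5 of 26 (11 and 5 adjusted over the list alone; camera adjusted p = 0.0219), and lysosome and phagocytosis genes lower for 15 and higher for 4 of 32 (15 and 4 adjusted over the list alone; camera adjusted p = 0.00832), with the cathepsin genes Ctsb (-3.40) and Ctsd (-1.79) lower. These 3 lists had adjusted p = 0.446 with an estimated correlation. Without a low-count filter the adhesion, lysosome and primary granule lists lost their calls (adjusted p = 0.0803, 0.0773 and 0.0575), and the adhesion list also with DESeq2 size factors (0.0518). With the strict filter the T and NK cell and stroma lists lost theirs (adjusted p = 0.375 and 0.0764). Lists that were not called were the progenitor list (6 higher and 12 lower of 25), the AML1-ETO associated list (7 and 6 of 20), plasma cell genes (2 and 5 of 10), megakaryocyte genes (5 and 5 of 13), mast cell, basophil and eosinophil genes (5 and 2 of 18; 4 and 1 adjusted over the list alone) and glycolysis genes (7 and 4 of 20; 6 and 4 adjusted over the list alone), and the first 4 had the same numbers adjusted over the list alone. The progenitor list was called without library 1 or 3 of CD43++ckit+, any one of the CD43+ckit- libraries or library 3 of CD43-ckit- (adjusted p from 0.0208 to 0.0472), and with library totals (0.00686). The plasma cell list was called without library 3 of CD43++ckit+, library 1 or 2 of CD43+ckit- or library 3 of CD43-ckit- (adjusted p from 0.0318 to 0.0494), and with library totals (0.0171). The glycolysis median was 0.42 with a mean of -0.09. Cdkn1a, a cell cycle inhibitor on the AML1-ETO associated list, was lower in CD43++ckit+ (-4.91), and Pou4f1 on that list was higher (2.95).

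**Figure D3:**
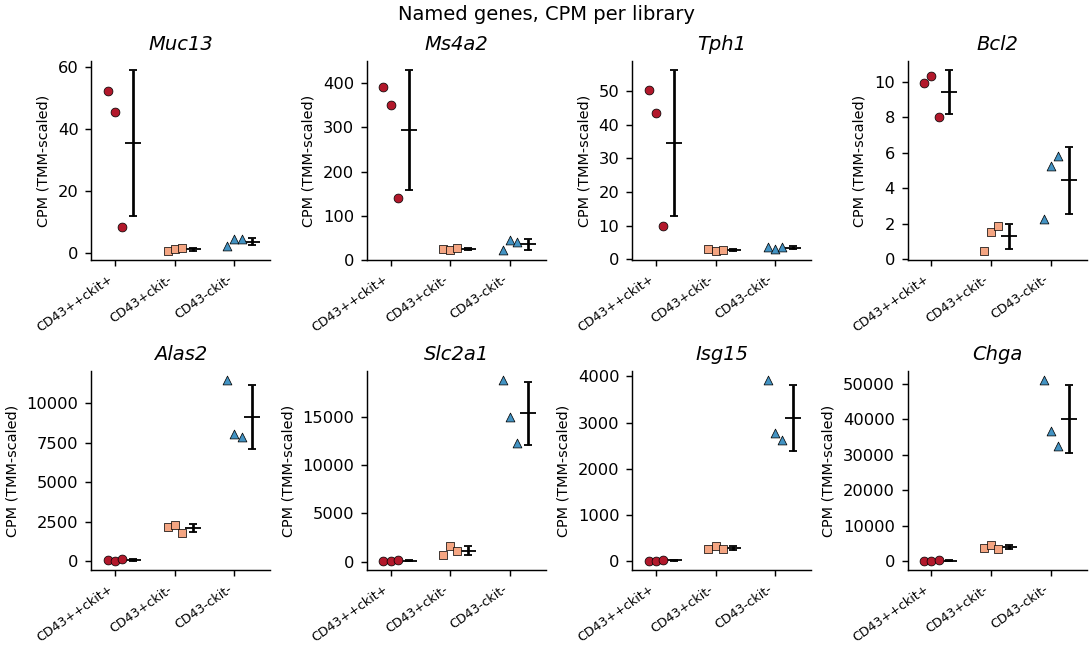
CPM per library (y axis, TMM-scaled, separate scale for each gene) of 8 named genes in the 3 populations (x axis), with points for libraries and bars for mean ± SD of 3 libraries. Muc13, Ms4a2, Tph1 and Bcl2 are highest in CD43++ckit+, where library 3 is the lowest of the 3, and Alas2, Slc2a1, Isg15 and Chga are highest in CD43-ckit-.

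In all, 8471 genes were called between CD43++ckit+ and CD43-ckit-, 4989 higher and 3482 lower, and the CPM of the 2 populations did not overlap for 73.2% of genes, against 10% by chance. Higher calls made up 58.9% with TMM scaling, 49.5% with DESeq2 size factors and 82.2% with library totals, and the median log2 fold change of all genes was 0.19, -0.05 and 1.11 with these scalings.

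CD43+ckit- cells had more transcript of cell cycle and respiration genes than CD43-ckit- cells. They had less of stress genes and of genes of monocytes, granules, dendritic cells, B cells and stroma. Levels of some of these lists were low: CD43+ckit- library means were 0.42, 1.23 and 0.96 log2 CPM for dendritic cell genes. For stroma genes they were -0.38, -0.059 and 0.084. Of the 23 lists 21 were called, 3 of them higher and 18 lower in CD43+ckit-. The largest increases were in Myh7b (2.70), the calcium channel gene Cacna1c (2.27) and the epithelial transcription factor gene Ehf (2.25). Among the largest decreases were Vgf (-6.42), Tecta (-6.28) and Hmox1, haem oxygenase (-5.39). DNA replication genes were higher for 30 of 32 and lower for 1 (30 and 1 adjusted over the list alone), including Ccne1 (1.86) and Cdc6 (1.73), with a median of 1.39 (camera adjusted p = 5.29e-08; adjusted p = 0.365 with an estimated correlation). Mitosis genes were higher for 29 of 32 and lower for 1 (29 and 1 adjusted over the list alone), including Dlgap5 (1.54) and Ccna2 (1.32) (camera adjusted p = 8.66e-07; adjusted p = 0.365 with an estimated correlation). Respiration genes were higher for 21 of 32 and lower for 0 (23 and 0 adjusted over the list alone), including Ndufs3 (1.25) and Cs, citrate synthase (1.08) (camera adjusted p = 2.65e-05; adjusted p = 0.365 with an estimated correlation).

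Immediate early and heat shock genes were lower in CD43+ckit- for 16 of 22 and higher for 0 (18 and 0 adjusted over the list alone), including Junb (-3.81) and Zfp36 (-3.30), and interferon response genes were lower for 12 of 31 (11 adjusted over the list alone), including Isg15 (-3.41); camera adjusted p = 1.73e-07 and 0.0003. Each had adjusted p = 0.365 with an estimated correlation. Monocyte and macrophage genes were lower for 18 of 28 (also 18 adjusted over the list alone), including Lgmn (-4.28), Axl (-2.83) and the mannose receptor gene Mrc1 (-2.46), and B-lineage genes were lower for 13 of 23 (22 adjusted over the list alone); camera adjusted p = 8.66e-07 and 6.72e-06. Here again adjusted p = 0.365 with an estimated correlation held for each list. Other cell type lists moved with these. Primary granule genes were lower for 8 of 14 (10 adjusted over the list alone), with a median of -2.89 (camera adjusted p = 0.000619). Dendritic cell and MHC class II genes were lower for 9 of 16 (10 adjusted over the list alone; camera adjusted p = 0.000591), and stroma and endothelium genes for 7 of 13 (8 adjusted over the list alone; camera adjusted p = 0.00568). Each had adjusted p = 0.365 with an estimated correlation. The neutrophil list had a median of -2.16 with 1 of 31 genes called lower, also when adjusted over the list alone (camera adjusted p = 0.000314; adjusted p = 0.532 with an estimated correlation). Lysosome and phagocytosis genes were lower for 14 and higher for 3 of 32 (camera adjusted p = 0.00124), and glycolysis genes lower for 8 and higher for 1 of 20 (camera adjusted p = 0.00354). BCL2 family genes were lower for 7 and higher for 2 of 13 (camera adjusted p = 0.0263). These 3 lists had the same numbers adjusted over the list alone and adjusted p = 0.365 with an estimated correlation. Adhesion and homing genes were lower for 6 and higher for 1 of 26 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00575), and mast cell, basophil and eosinophil genes lower for 3 and higher for 2 of 18 (also adjusted over the list alone; camera adjusted p = 0.0206). Both had adjusted p = 0.365 with an estimated correlation. With the neutrophil list mean as a covariate the neutrophil, stroma, BCL2 family and adhesion lists lost their calls (adjusted p = 0.702, 0.0568, 0.056 and 0.0711). With the strict filter the stroma and mast cell lists lost theirs (adjusted p = 0.117 and 0.119).

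The AML1-ETO associated, plasma cell and T and NK cell lists were called narrowly between CD43+ckit- and CD43-ckit- (camera adjusted p = 0.0469, 0.0469 and 0.0332; adjusted p = 0.365, 0.365 and 0.596 with an estimated correlation). Lower and higher members numbered 7 and 4 of 20, 3 and 1 of 10, and 3 and 2 of 24 (7 and 4, 2 and 0, and 1 and 2 adjusted over each list alone). All 3 lost the call with DESeq2 size factors (adjusted p = 0.0724, 0.0752 and 0.0957), without a low-count filter (0.207, 0.118 and 0.0961) and with the neutrophil covariate (0.0711, 0.222 and 0.847). The plasma cell list also lost it with the strict filter (adjusted p = 0.0894). The T and NK cell median turned from -1.49 to 0.29 with the covariate, and was -0.18 with the strict filter (adjusted p = 0.768). The AML1-ETO associated list also lost it without library 1 or 2 of CD43++ckit+, library 1 of CD43+ckit- or any one of the CD43-ckit- libraries (adjusted p from 0.0508 to 0.0652). The plasma cell list lost it without library 1 of CD43++ckit+, library 1 of CD43+ckit- or any one of the CD43-ckit- libraries (adjusted p from 0.0506 to 0.0676). The T and NK cell list lost it without library 1 of CD43+ckit- or library 2 or 3 of CD43-ckit- (adjusted p from 0.0562 to 0.107). Progenitor genes were lower for 14 of 25 and higher for 1 (14 and 1 adjusted over the list alone), including Gata2 (-1.64), Adgrg1 (-1.37) and Tal1 (-1.30) (camera adjusted p = 0.00124; adjusted p = 0.205 with an estimated correlation). Erythroid genes split: 10 were lower, with Bpgm at -3.81, 5 were higher, with Icam4 at 1.42, and 15 were not called (5 and 10 adjusted over the list alone). The erythroid list was called in the unblocked fit (camera adjusted p = 0.0439; adjusted p = 0.596 with an estimated correlation) and not with same-numbered libraries as blocks, either in a fit of these 2 populations (adjusted p = 0.177) or over all 9 libraries (0.0579). It was also lost without library 1 or 2 of CD43++ckit+, library 2 or 3 of CD43+ckit- or library 1 of CD43-ckit- (adjusted p from 0.0506 to 0.484). With library totals its median was 0.36 (adjusted p = 0.275). MYC and ribosome biogenesis genes, with 3 higher and 1 lower of 30 (0 and 1 adjusted over the list alone), were not called in the unblocked fit (adjusted p = 0.17) and were with blocks in the fit of these 2 populations (adjusted p = 0.0455), but not with blocks over all 9 libraries. They were also called without library 1 of CD43+ckit- (0.0296). In all 6523 genes were called, 3893 higher and 2630 lower, of which 3366 changed at least 2-fold. Higher calls made up 59.7% with TMM scaling, 45.8% with DESeq2 size factors and 85.2% with library totals.

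**Figure D4:**
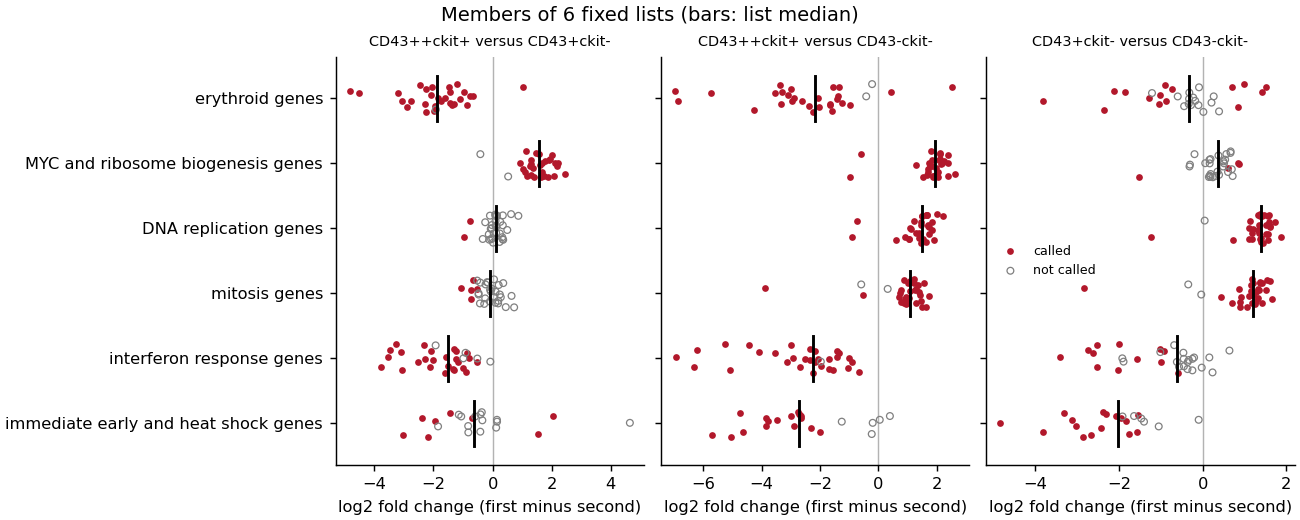
Log2 fold changes (x axis, first-named population minus second) of the members of 6 fixed lists (y axis) in the 3 comparisons. Filled points are genes called at the adjusted p threshold, open points are not called, and black bars are list medians. Replication and mitosis medians lie near 0 in the first comparison and above 1 in the others, and erythroid medians are -1.88, -2.15 and -0.32.

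Genes that set CD43++ckit+ apart from both other populations numbered 3857, of which 2048 were higher and 1809 lower in both comparisons, and 210 further genes went in opposite directions. The higher genes were led by C2cd4a, Tph1, Muc13, Ms4a2, Tgfa and the organic cation transporter gene Slc22a3 (3.26 and 2.94 against CD43+ckit- and CD43-ckit-). The lower genes were led by Adam33, Mmel1, Btnl10, Hbq1b, Alas2 and Chga. The comparisons share the CD43++ckit+ libraries. Simulated groups with no effect gave an overlap of at most 0 genes in each direction over 10 simulations, which says little about lists that hold real effects. Independent lists of these sizes would share 980.9 higher and 701.5 lower genes. With 3 shared libraries they could not be divided with 2 in each part, so part of the excess may come from them. Without the library of each population that correlated least, 6877 genes set CD43++ckit+ apart.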

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

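The block within 2 groups, the neutrophil covariate, leaving out the least correlated libraries, and thinning were chosen after the results were seen. Over all alternatives 7352 values of named genes kept direction and side of the threshold, 213 lost a call, 106 gained one, 7 reversed and 18 turned sign without a call on either side. For lists, judged by the direction that the list test gave, 1318 kept both, 115 lost a call and 47 gained one. A further 5 reversed and 33 turned direction without a call. Leaving out each library gave 3493 to 5919 called genes for CD43++ckit+ versus CD43+ckit-, 7366 to 9534 for CD43++ckit+ versus CD43-ckit- and 5080 to 7800 for CD43+ckit- versus CD43-ckit-. The joint test then gave 8337 to 10504, and 2697 to 4885 genes set CD43++ckit+ apart.

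A 2-fold minimum left 2676 genes for CD43++ckit+ versus CD43+ckit- and 3366 for CD43+ckit- versus CD43-ckit-, since it adds a condition. Camera with an estimated correlation called 0, 0 and 0 lists in place of 6, 17 and 21. Only this setting was changed between the 2 runs, which does not show that the estimate itself ended the calls. Most lists called against CD43-ckit- shared the same adjusted p there (0.446 or 0.365), which therefore does not measure each list on its own. For CD43++ckit+ versus CD43+ckit- the estimate was 0.508 for the erythroid and 0.6065 for the MYC list, against the preset 0.01. Between CD43+ckit- and CD43-ckit- it was -0.00592 for the progenitor list, which also lost its call. A high estimate thus does not account for every loss. Without the least correlated libraries 8557 genes were called for CD43++ckit+ versus CD43+ckit-, and 6877 set CD43++ckit+ apart; the cause was not tested. The same alternative put Runx1t1 at 0.35 for CD43++ckit+ versus CD43-ckit- and Nkg7 at -0.86 for CD43++ckit+ versus CD43+ckit-. The neutrophil covariate left 10 lists for CD43++ckit+ versus CD43-ckit-. There camera's direction turned for the neutrophil list (median 0.24) and for the primary granule list, whose median stayed negative (-0.10). Between CD43+ckit- and CD43-ckit- it turned for the neutrophil (0.097) and T and NK cell (0.29) lists. None of these was then called. This covariate is the neutrophil list's own mean, so by construction it removes that list's change. With the strict filter, which tests fewer genes, camera's direction also turned for the T and NK cell list between these populations. Its median stayed negative (-0.18), and it was not called (adjusted p = 0.768).

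With library totals, Runx1t1 stood at 0.93, Ap3s1 at 0.28, Xbp1 at 0.12 and Apoe at 0.057 for CD43++ckit+ versus CD43-ckit-, where the median of all genes was 1.11. Xbp1 stood at 0.087 between CD43+ckit- and CD43-ckit-. Each was of the other sign with TMM.

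A replicate block over all libraries called 4804, 8836 and 6576 genes in the 3 comparisons. Same-numbered CD43++ckit+ and CD43+ckit- libraries correlated at 0.423, -0.597 and 0.375, and CD43++ckit+ and CD43-ckit- libraries at 0.242, -0.302 and 0.242. The pairing rule was thus not met there. For CD43++ckit+ versus CD43+ckit- the block over all libraries added calls of the neutrophil (adjusted p = 0.02) and mast cell (0.0409) lists. Among other changes, the block within 2 groups ended the Runx1 call there (adjusted p = 0.0584). For CD43++ckit+ versus CD43-ckit- the block over all libraries called Runx1 (adjusted p = 0.0362). Between CD43+ckit- and CD43-ckit- the block within 2 groups called 8098 genes. It changed the calls of Spn and of the erythroid and MYC lists, given above. It also ended the call of Rag1 (adjusted p = 0.231) and made calls of Clec4d, Trem3, Trem1, Il2rb and Prss34 (adjusted p from 2.55e-66 to 0.000772). For Prss34 the log2 fold change was -3.95, against -3.73 in the main fit (adjusted p = 0.0549). So small a value from 6 libraries calls for caution with the p-values and calls of this fit. Within 2 groups the block changed no other call of a gene or list followed in that comparison. The non-robust and limma-voom fits do not enter camera, and leaving out haemoglobin, immunoglobulin and mitochondrial genes removed few tested genes, so these say little about stability.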

Other observations

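The p53 target test, both granulocyte tests, the Hbq1b test and the thinning test were chosen after the result was seen. Sets of p53 and ATF4 target genes were assembled once Cdkn1a, Bbc3 and Ppp1r15a had been seen, and share no member with the 23 lists. Pmaip1, which is on a fixed list, was taken out of the p53 set after a first run, with the same outcome. The hypothesis was that p53 targets as a group may be higher in CD43-ckit- than in CD43++ckit+. Of 27 tested genes 17 (62.96%) were called higher in CD43-ckit- and 3 lower (camera adjusted p = 0.000424; adjusted p = 0.0979 with an estimated correlation). Trp53inp1 differed by -4.71, Mdm2, the p53 ubiquitin ligase, by -3.57 and Phlda3 by -1.77 (log2, CD43++ckit+ minus CD43-ckit-). Fdxr (1.52) and Ddb2 (0.78) went the other way. With DESeq2 size factors 17 members were higher in CD43-ckit- and 1 lower, and with library totals 10 were higher and 8 lower. The prediction asked for most members to be called higher in CD43-ckit-, which library totals did not give. No list test was run with library totals. The list median was -1.16 with TMM and -0.21 with library totals, where the median of all genes was 0.19 and 1.11. Against CD43+ckit-, too, 17 of the 27 were called higher in CD43-ckit- and 2 lower (camera adjusted p = 8.33e-06; adjusted p = 0.0436 with an estimated correlation), and 10 higher and 5 lower with library totals. Between CD43++ckit+ and CD43+ckit- 3 were called higher and 4 lower in CD43++ckit+ (camera adjusted p = 0.657), and 8 higher and 3 lower with library totals.

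ATF4 drives the integrated stress response, and its targets were the other hypothesis. Of 23 tested genes 12 (52.17%) were called higher in CD43-ckit- and 3 lower (camera adjusted p = 0.00172; adjusted p = 0.159 with an estimated correlation). Atf5 differed by -4.87 and Trib3 by -2.51, while Asns, asparagine synthetase, was higher in CD43++ckit+ (1.02). With DESeq2 size factors 14 were higher in CD43-ckit- and 3 lower, and with library totals 9 and 8, where the list median was -0.01. Library totals thus did not give most members higher here either. Against CD43+ckit- 11 were higher in CD43-ckit- and 2 lower (camera adjusted p = 0.000613; adjusted p = 0.128 with an estimated correlation), and 8 higher and 6 lower with library totals. Between CD43++ckit+ and CD43+ckit- 3 were higher and 7 lower in CD43++ckit+ (camera adjusted p = 0.307), and 5 higher and 7 lower with library totals. Sesn2 (-4.65) is in both sets.

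Granulocyte genes differed between libraries of one population: S100a8 ranged from 19.0 to 1192 CPM in CD43++ckit+, from 89.6 to 774.2 in CD43+ckit- and from 869.8 to 4445 in CD43-ckit-. The differences were not confined to these genes. In CD43++ckit+ library 3 was highest and library 2 lowest for the neutrophil, monocyte, dendritic cell, B-lineage, T and NK cell and stroma lists. In CD43-ckit- library 1 was lowest for the neutrophil list (5.82 log2 CPM) but highest for the B-lineage list (4.03). An animal shared by same-numbered libraries of all 3 populations stays open: library 2 of CD43++ckit+ correlated negatively with its namesakes (-0.597 and -0.302), but the other 7 same-numbered pairs ranged from 0.242 to 0.506, and a single library decides nothing. Granulocytes of one composition in different amounts may account for the differences in granulocyte genes. The SD of CPM ranked the 31 neutrophil genes alike in each pair of populations (lowest Spearman rho 0.9415, across genes, which are not independent). The other 12542 genes reached 0.697 to 0.821, so such a rank can follow from abundance alone and leaves this open. CD43 and c-Kit gates need not remove granulocytes, and differences between leukaemias were not tested.

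Adult alpha and beta globin rows held 13 counts over all libraries, although Slc4a1 and Alas2 were abundant in CD43-ckit-. Cells without adult globin transcripts stay open: the theta globin gene Hbq1b differed by -7.391 between CD43++ckit+ and CD43-ckit-, which does not bear on the adult genes. Loss of reads to near-identical copies as the whole cause could not be settled for the alpha genes. Of the 50-base words of Hba-a1, 27.73% occur in no other gene of the reference transcripts, while the row held at most 4 counts in a library. That share goes against this cause, but for Hba-a2 it was 10.71%. Words were matched exactly, and the annotation of the counts is unknown. The alpha and beta genes were judged apart only after the values were seen. For the beta genes this cause also stays open: the share was 46.79% for Hbb-bs, but the counted annotation held Hbb-b1 and Hbb-b2, which that reference lacks. Globin depletion and overlapping gene models were not tested.

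More genes were called higher than lower in CD43++ckit+ against CD43-ckit- with TMM (58.9%), but not with DESeq2 size factors (49.5%) or DESeq2 (48.4%). Lower totals of the CD43-ckit- libraries are argued against by counts thinned to one total, with 58.06% higher. Thinning did not even out the depth left for most genes. In the unthinned counts TMM factors were 1.26 to 1.41 in CD43++ckit+ and 0.589 to 0.776 in CD43-ckit-. Lower depth of the CD43-ckit- libraries in that sense stays open. Abundant genes taking the counts there could not be settled: the 100 most abundant CD43-ckit- genes held 31.9% to 35.7% of counts in that population and 7.27% to 8.68% in CD43++ckit+. Library totals without them gave 72.78% higher, between 82.2% for full totals and 58.9% for TMM. A difference in RNA content between the populations was not tested.

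Of 100 splits drawn from 280 of the 9 libraries, only 1, the real one with 9401 genes, gave as many genes in the joint test. Chance regrouping of these libraries would thus rarely reach that count. Every other split mixes the sorted populations, and the test does not show that the libraries came from separate animals. The highest other split gave 3941. Of the 100, 47 part every same-numbered pair of CD43+ckit- and CD43-ckit-, the real one included, and the highest other of these also gave 3941. In fits of 6 libraries with edgeR there are 10 splits, too few for a share under 0.05, and 1, the real one, had as many genes in each comparison. For CD43++ckit+ versus CD43+ckit- the real split gave 5571 genes and the highest other 0 (1820 at an unadjusted p under 0.05). For CD43++ckit+ versus CD43-ckit- these were 7791 and 0 (613 unadjusted). For CD43+ckit- versus CD43-ckit-, which the rule above took as paired, they were 6515 and 0 (634 unadjusted). Of its splits 4 part every pair, the real one included, and the highest other of these gave 0 (14 unadjusted).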
